A study of Ovis aries with 6 samples.

How the data were processed

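Poly(A) RNA of primary Hu sheep granulosa cells, captured with oligo(dT) beads and primed with random hexamers per the labels' protocols, was sequenced from 3 libraries transfected with INHBA siRNA and 3 with a negative control. The aligner, counter, test and genome build of the authors are not given in the sources used here, and no coordinates are printed. Per the file headers, the first deposited sheet holds a raw read count and an FPKM value per gene and library, made by the authors, together with the authors' own false discovery rate (an adjusted p-value) and log2 fold change. In the values, the highest deposited false discovery rate was 0.0090 and the smallest absolute log2 fold change 1.00, so the sheet holds only genes that the authors called. It has 1620 genes, of which 1566 carry a symbol or LOC name and 54 an identifier of an unannotated gene; 4 lines held no complete gene and were left out. The other deposited sheets place called genes under keyword or KEGG pathway sections and were used only for which genes a section holds. In the FoxO section 1 identifier was damaged and matched no gene. The 12 sections of the follicular development sheet repeat those of the KEGG sheet and were not tested again.

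Counts were tested with edgeR 4.0.16 (R 4.3.3, glmQLFit and glmQLFTest, filterByExpr with its minimum count of 10, no block), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The standard error of a log2 fold change is its absolute value over the square root of F. The scaling is a departure from the plan. TMM had been chosen before the data were examined, but it assumes that most genes in a table do not change, and every listed gene had been selected for change. Library sizes were therefore recovered, after the table had been seen, from the ratio of count to FPKM, which is proportional to transcript length and mapped reads: the median over 702 genes with over 200 counts in every library gave each library's depth relative to the first siNC library. This equals scaling to mapped reads and does not correct for a few genes taking a large share of them. The report gives the main changes under TMM. FPKM values are given as mean ± SD with n = 3.

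The direction of each of 25 gene lists, fixed before the data were examined, was compared with that of the other passing genes by Fisher's exact test (two-sided, lists with at least 5 passing members, 12 lists, Benjamini-Hochberg). Membership cannot be tested against genes that are not listed, and the planned camera gene set test was not run because it is void on a table of called genes. Named genes followed a rule fixed in advance: INHBA, INHA, INHBB and FST where listed; among genes with a symbol, separated groups and at least 1 FPKM in a group, the 6 largest rises and falls; from each list the 2 members with the smallest adjusted p, or 4 where its test passed; and the 3 largest rises and falls of the PI3K-AKT sheet. Other genes were named after their values were seen: ACVR1B, NOG, GADD45G, E2F1, ESR1, HSD17B1, CSF1R, KDR and VWF, where a count is spelled out, and those of the closing section. Some genes that the rule takes are not reported here.

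Replicates were compared before averaging. Counts of replicate pairs differed by more than sampling noise, with a mean chi-square per gene of 5.57 to 9.36 in siNC and 19.1 to 51.9 in siINHBA, so no library was a copy of another. The median coefficient of variation was 7.90% in siNC and 16.9% in siINHBA.

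The scripts were tested on simulated counts for siINHBA against siNC (1620 genes, 200 changed). At an adjusted p of 0.05, 40% of genes changed by 1.5-fold, 92% of those changed by 2-fold and 98% of those changed by 3-fold or 4-fold were recovered, and 2.38% of calls were false. When all 1620 genes were simulated with the fold changes of the authors' deposited table, the recovered depth had a median bias of -0.0018 on the log2 scale and TMM of 1.01; this takes the authors' fold changes as true, and the simulated depths were known. With directions drawn at random gene by gene, 4 of 100 draws had any list past the threshold. Genes of a list can move together, which these draws did not imitate. The Fisher's exact tests and the length-matched draws of the closing section likewise treat genes as independent, so their p-values do not measure the spread between libraries. Alternatives were DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) with other pseudocounts, filters, scalings, priors and weights, a replicate block, a log2 fold change of at least 1, and leaving out each library.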

Results

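RNA sequencing was used to compare primary granulosa cells of Hu sheep (Ovis aries), the somatic cells that surround the oocyte and make oestradiol and inhibins, after transfection with a small interfering RNA against INHBA (siINHBA) or with a negative-control RNA (siNC). INHBA encodes the beta A subunit shared by activin A and inhibin A. The cells came from follicles of at least 3 mm and RNA was taken 24 h after transfection. Each group held 3 libraries. The labels do not say whether these were separate cultures or animals, so the p-values of single genes measure only the spread between these libraries, which may be technical. The deposited table lists 1620 genes, each one called changed by the authors, so nothing can be said here about genes outside it. Counts over these genes summed to 2781548, 2948524 and 2898268 in the siNC libraries and to 1590871, 1883770 and 2042924 in the siINHBA libraries. The depth of whole libraries, recovered from the ratio of count to FPKM, ran from 0.952 to 1.17 times that of the first siNC library.

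The siRNA target was measured first. INHBA fell from 20.5 ± 1.75 FPKM in siNC to 7.36 ± 0.77 FPKM in siINHBA (mean ± SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The siINHBA level was 35.9% of the control level, and every siINHBA library lay below every siNC library. Its log2 fold change was -1.49 (SE 0.14, edgeR quasi-likelihood adjusted p = 3.9e-06). INHA, the alpha subunit of the inhibins, fell as well, from 9.79 ± 0.66 to 2.82 ± 0.51 FPKM, a log2 fold change of -1.79 (SE 0.18, edgeR adjusted p = 7.1e-06). INHBB and FST were not among the listed genes. When edgeR's TMM factors were taken over the listed genes in place of the recovered depth, the INHBA log2 fold change was -0.41 (edgeR adjusted p = 0.018).

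**Figure D1:**
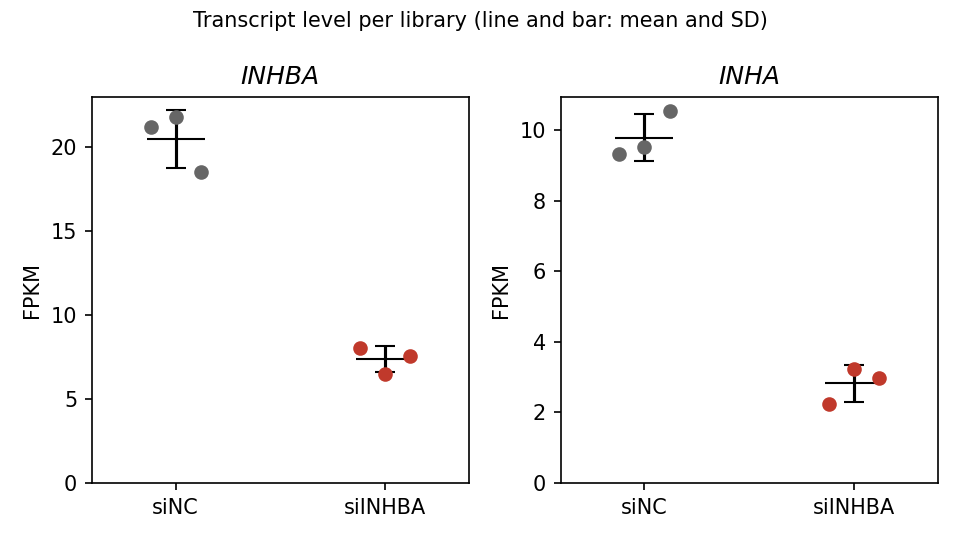
FPKM of INHBA (left) and INHA (right) in each library, with points for the 3 siNC and 3 siINHBA libraries and lines for the group mean and SD. INHBA fell from a mean of 20.5 to 7.36 FPKM and INHA from 9.79 to 2.82 FPKM, with no overlap between groups.

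Of the 1620 listed genes, 1065 (65.7%) were lower and 555 (34.3%) higher in siINHBA, with a median change of 2.64-fold for the lower and 2.80-fold for the higher genes. All 1620 passed an adjusted p of 0.05 (edgeR quasi-likelihood, highest adjusted p = 0.015), a recount within the authors' own selection. The groups did not overlap for 1619 genes, against 10% by chance, although the selection favours such genes. The split depended on the scaling. In limma over 1373 genes, libraries scaled to a common median gave 803 lower and 459 higher genes. Quantile normalization gave 901 lower and 458 higher. TMM over the listed genes, the scaling chosen before the data were examined, raised the median log2 fold change by 1.09 and gave 364 lower and 555 higher genes, with 701 not past the threshold. The number past the threshold as higher stayed at 555. Genes said below to turn higher with TMM changed sign without passing as higher. The fold changes in the authors' deposited table had the direction of the recovered-depth fit for all 1620 genes, with a median difference of 0.024 on the log2 scale.

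Among genes with a symbol, the largest rise was that of MMP13, a collagenase. It rose by 6.23 on the log2 scale (SE 0.52), from a siNC level of 0, 2 and 2 counts that leaves the fold imprecise. CCL20, a chemokine, rose from 2.42 ± 0.80 to 63.4 ± 7.73 FPKM, and SLPI, a secreted protease inhibitor, from 1.70 ± 0.17 to 37.4 ± 4.23 FPKM (mean ± SD, n = 3). IL23A, IRAK3 and NEURL3 followed with log2 fold changes of 4.35 (SE 0.43), 4.10 (SE 0.55) and 4.09 (SE 0.31). These 3 genes had at most 20 counts in any siNC library, so their folds are imprecise as well. The largest falls were in CENPF, a kinetochore protein, at -3.95 (SE 0.25), and in MAP6, a microtubule-binding protein, at -3.88 (SE 0.29). DEPDC1 had a log2 fold change of -3.36, the proliferation marker MKI67 of -3.36, the heparan sulphate sulphatase SULF2 of -3.24 and the spindle protein ASPM of -3.22. The edgeR adjusted p of these 12 genes was at most 4.1e-05.

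Genes of cell division fell together. Of the 35 genes in the mitosis and G2/M list, 34 were listed and all 34 were lower, by a median of 4.69-fold, against 65.0% of the other listed genes (two-sided Fisher's exact test, adjusted p = 5.9e-06 over 12 lists). MKI67 fell from 6.93 ± 0.54 to 0.67 ± 0.09 FPKM, TOP2A, the topoisomerase that untangles chromosomes, from 6.78 ± 0.45 to 1.03 ± 0.12, PRC1 from 16.4 ± 0.91 to 2.77 ± 0.11 and the mitotic kinesin KIF20A from 13.5 ± 0.44 to 2.22 ± 0.29 FPKM. The DNA replication and G1/S list had 12 of its 36 genes listed, all 12 lower, by a median of 3.03-fold (Fisher's exact adjusted p = 0.033). The ribonucleotide reductase subunit RRM2 had a log2 fold change of -2.39 (SE 0.20), UHRF1 of -1.86 (SE 0.16), and the replicative helicase subunits MCM3 and MCM5 of -1.70 (SE 0.13) and -1.62 (SE 0.12). Under TMM over the listed genes all 34 mitosis genes stayed lower and 29 passed. Of the 12 replication genes 11 stayed lower and 6 passed. E2F1, at -1.08 on the log2 scale with the recovered depth, changed sign under the median shift of 1.09.

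In the growth arrest list, which holds inhibitors of cyclin-dependent kinases and genes induced by DNA damage, 6 of 24 genes were listed. Of these 5 were higher and 1, GADD45G, was lower (Fisher's exact adjusted p = 0.048). CDKN1A, which encodes p21, rose from 177 ± 6.98 to 489 ± 58.5 FPKM. BTG2 and CDKN2C rose by 1.38 and 1.19 on the log2 scale. With TMM over the listed genes the direction test no longer passed (adjusted p = 0.23), although the 5 genes were still higher, and GADD45G turned from lower to higher. Of 27 apoptosis regulators 6 were listed, 4 higher and 2 lower (Fisher's exact adjusted p = 0.23), with BAX at 1.21 on the log2 scale. With TMM 5 of these 6 passed.

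Inflammatory genes rose. The list of inflammatory cytokines and NF-kB genes had 15 of 24 members listed, all 15 higher, by a median of 5.12-fold (Fisher's exact adjusted p = 1.1e-06). Besides CCL20, the adhesion molecule ICAM1 rose from 11.1 ± 1.59 to 60.3 ± 14.0 FPKM, the NF-kB inhibitor NFKBIA from 13.0 ± 2.31 to 72.5 ± 8.46 FPKM and SOD2, the mitochondrial superoxide dismutase, from 33.5 ± 3.08 to 114.5 ± 11.02 FPKM. The interferon and foreign RNA list had 5 of 35 members listed and all 5 were higher (Fisher's exact adjusted p = 0.019). They included the chemokine CXCL10, with a log2 fold change of 3.52 (SE 0.32), and HERC5, IFI44L and IRF7, at 1.50, 1.35 and 1.11. With TMM the interferon direction test did not pass (adjusted p = 0.23) and all 5 genes were still higher. The leukocyte marker CSF1R, the only one of 18 listed, was lower, at 0.44 FPKM in siNC and 0.20 FPKM in siINHBA, but its log2 fold change was -0.02 with TMM.

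**Figure D2:**
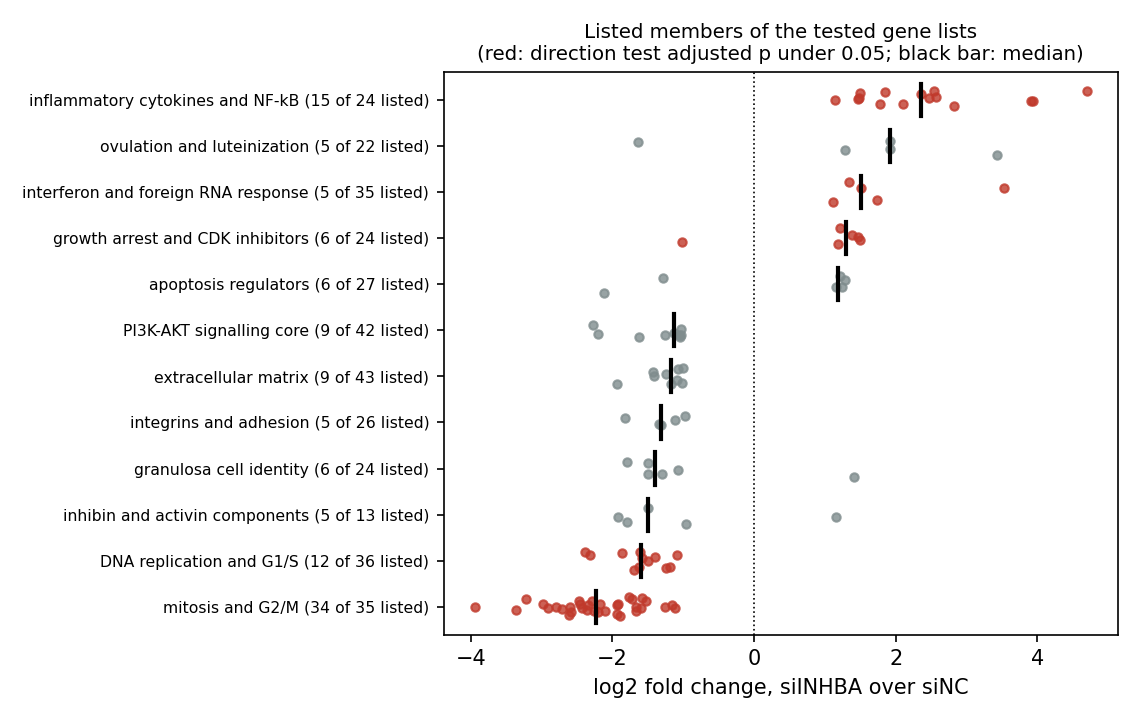
Log2 fold change (siINHBA over siNC, x axis) of every listed member of the 12 tested gene lists, with 1 point per gene, a black bar at the median and red for lists whose direction test had an adjusted p under 0.05. The 34 mitosis genes all lie below 0 and the 15 inflammatory genes all above 0. TMM over the listed genes would shift the points up by about 1.09, which turns 13 of the plotted genes from lower to higher, among them 4 PI3K-AKT and 4 extracellular matrix genes.

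The few listed genes of granulosa cell function were mostly lower, without a direction that stood apart from the other listed genes. The granulosa identity list had 6 of 24 genes listed, and 5 of the 6 were lower (Fisher's exact adjusted p = 0.67). The lower genes included INHA, the siRNA target INHBA, NR5A1 and ESR1, and HSD17B1 was higher. With TMM 3 of the 6 passed in their direction, and NR5A1 did not (adjusted p = 0.33). ESR1, at -1.07 on the log2 scale with the recovered depth, changed sign. CYP11A1, which makes pregnenolone from cholesterol, fell from 141.7 ± 5.43 to 51.6 ± 6.45 FPKM, and NR5A1, a transcription factor of steroidogenic genes, from 26.9 ± 1.18 to 10.9 ± 2.36 FPKM. The steroid synthesis list had 4 of 23 genes listed, 3 lower and 1 higher. The cholesterol list had 3 of 26 listed, all lower, with ABCG1 at -1.77 on the log2 scale. Both lists were too short to test, and with TMM 2 of the 4 and 1 of the 3 genes passed. The ovulation list had 5 of 22 genes listed, 4 of them higher (Fisher's exact adjusted p = 0.075), among them PTX3 at 1.29 on the log2 scale. PLAT, tissue plasminogen activator, was lower at -1.64.

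The lists of the activin, TGF-beta and BMP pathways did not pass a direction test or were too short for one. The inhibin and activin list had 5 of 13 genes listed. Of these 4 were lower, the siRNA target INHBA among them, and 1, ACVR1B, was higher (Fisher's exact adjusted p = 0.67). The SMAD response list had 3 of 24 genes listed, 2 lower and 1 higher. The BMP list had 4 of 22 listed, 3 lower and 1, NOG, higher. Both lists were too short to test. TGFBR2, BMPR2 and BMPR1A had log2 fold changes of -1.33 (SE 0.12), -1.63 (SE 0.19) and -1.54 (SE 0.21). With TMM BMPR2 passed, and TGFBR2 (adjusted p = 0.11) and BMPR1A (adjusted p = 0.066) did not. FSTL1 and PMEPA1 were at -0.96 and -1.02, and both turned to just above 0 with TMM, at 0.12 and 0.07.

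The PI3K-AKT core list had 9 of 42 genes listed, all lower, and the extracellular matrix list 9 of 43, all lower, each short of the threshold (Fisher's exact adjusted p = 0.055 for each). Counting only genes with an absolute log2 fold change of at least 1, which left 10 lists to test, both passed (adjusted p = 0.045 for each). PIK3R3, a regulatory subunit of PI3-kinase, and the receptor KIT had log2 fold changes of -2.28 (SE 0.16) and -2.21 (SE 0.19), and the basement membrane genes COL4A3 and NID2 of -1.94 (SE 0.14) and -1.43 (SE 0.12). In the integrin and adhesion list 5 of 26 genes were listed, all lower (Fisher's exact adjusted p = 0.23), CDH2 at -1.32 and ITGB5 at -1.11. Under TMM 4 PI3K-AKT genes, 4 matrix genes and 1 adhesion gene turned higher, and 3 PI3K-AKT and 2 matrix genes passed as lower. Of the adhesion genes 0 passed with edgeR under TMM, against 1 at an unadjusted p under 0.05 and 1 with DESeq2 and its own size factors.

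Markers of other ovarian cell types that were listed were all lower: 3 of 19 for theca, stroma and smooth muscle, 2 of 14 for endothelium, 1 of 18 for leukocytes, 1 of 12 for oocytes and 2 of 12 for epithelium. These lists were too short to test, and 65.7% of all listed genes were lower. The oocyte marker was KIT, and both KIT and the stroma marker PDGFRB are also counted in the PI3K-AKT core list. DES fell from 40.1 ± 1.20 to 11.8 ± 1.35 FPKM, PDGFRB from 24.1 ± 0.95 to 7.82 ± 1.82, KRT19 from 15.1 ± 0.41 to 4.27 ± 0.82 and UPK1B from 17.9 ± 1.23 to 8.32 ± 0.89 FPKM. The endothelial genes KDR and VWF were low, at 0.30 and 0.33 FPKM in siNC and 0.05 and 0.13 FPKM in siINHBA. Among the remaining lists, RPL3 and RPL5 were the 2 of 30 ribosomal protein genes listed, at -1.27 and -1.54 on the log2 scale. SLC2A3 and BNIP3 of the glycolysis and hypoxia list rose by 1.86 and 1.54, where 3 genes were higher and 1 lower. VLDLR, the 1 stress response gene listed, rose by 1.90, and none of the 13 heat shock genes was listed. Under TMM over the listed genes 11 of the genes chosen by the naming rule no longer passed as lower, among them FSTL1, PMEPA1, TGFBR2, BMPR1A, NR5A1, CDH2, ITGB5, RPL3 and UPK1B. For every list all listed members also passed when adjusted over the list alone, which had to follow because every listed gene passed over the whole table.

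The authors' own pathway sheets were chosen on these samples, so they are not independent evidence of direction. Of 37 sections with at least 5 genes, 9 differed from the rest of the table (Fisher's exact test, Benjamini-Hochberg adjusted). The cell cycle sections had 14 genes higher and 76 lower by keyword (adjusted p = 0.0010) and 4 higher and 30 lower by KEGG (adjusted p = 0.022). All 21 genes of the focal adhesion keyword section were lower (adjusted p = 0.0017), whereas the 32 genes annotated to the KEGG pathway of that name had 6 higher and 26 lower (adjusted p = 0.13 over 141 annotated pathways). Of the 20 genes in the oocyte meiosis section 19 were lower (adjusted p = 0.019). The NF-kappa B section had 21 genes higher and 5 lower by KEGG (adjusted p = 4.7e-05) and 30 higher and 17 lower by keyword (adjusted p = 5.8e-04). The TNF sections had 21 higher and 9 lower by KEGG and 23 higher and 13 lower by keyword, and the chemokine section 19 higher and 13 lower. The PI3K-AKT sheet, with 48 genes, had 15 higher and 33 lower, against 540 higher and 1032 lower among the other genes (adjusted p = 0.97). It lacks 3 of the 51 genes in the KEGG section of that pathway, which had 15 higher and 36 lower (adjusted p = 0.85). Within it the largest rises were in IBSP, AREG and FLT3LG, at 3.46, 3.42 and 2.50 on the log2 scale, and the largest falls in ANGPT4, KIT and FGF22, at -3.21, -2.21 and -2.18.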

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

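The recovered-depth scaling and DESeq2 with that depth were chosen after seeing the data. The other settings were planned, but every edgeR setting except TMM itself used the recovered depth in place of the planned TMM. This includes the fits without a library and with a replicate block. TMM over the listed genes gave 919 passing genes in place of 1620, 364 of them lower (39.6%), and 3 lists past the direction test in place of 5; DESeq2 with its own size factors gave 914 genes, 359 lower (39.3%), and 3 lists. Under both, 5 growth arrest genes and 5 interferon genes were still higher but their direction tests did not pass (adjusted p = 0.23 for each with TMM and 0.20 for each with DESeq2), and FSTL1 (0.12 and 0.12) and PMEPA1 (0.067 and 0.065) turned positive. Both methods centre the table on its median gene, which by construction removes a shift shared by most listed genes. limma with a filter of 5 FPKM tested and passed 749 genes, 504 lower and 245 higher, because fewer genes were tested; with that filter, in limma or on the edgeR calls, 3 lists and 5 sections passed, and 7 replication genes lower (adjusted p = 0.12) and 4 interferon genes higher (too few to test) no longer passed. In limma with libraries scaled to one median, 5 of 6 growth arrest genes were higher (adjusted p = 0.056); the cause was not tested. The INHBA log2 fold change was negative and past the threshold in every setting that gave it. With TMM 7 of 32 sections passed. With an absolute log2 fold change of at least 1, 1583 genes and 7 of 10 lists passed, the PI3K-AKT and matrix lists among them (adjusted p = 0.045 for each), with fewer lists tested.

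Without each library in turn, 1618 to 1620 genes passed, of which 1063 to 1065 were lower and 555 higher (65.7% lower in each). INHBA lay between -1.64 and -1.38, and 5 lists and 9 sections passed. The mitosis, replication, inflammatory, growth arrest and interferon lists kept 34, 12, 15, 5 and 5 genes on their leading side. The authors had called every listed gene from these same 6 libraries, so these counts had little room to change. The 20 other settings gave 1076 values of named genes. The log2 fold change minimum, the authors' own calls and the 5 FPKM filter on edgeR calls gave none of these. Of the 1076 values 1056 kept their direction and their call, 16 no longer passed and 4 reversed (FSTL1 and PMEPA1, above). The labels state no pairing by replicate number, and the values leave it open. Libraries of the same number correlated at 0.07, 0.20 and -0.01, and those of different numbers at -0.15 to 0.10. With a replicate block 1620 genes passed in edgeR, 1065 lower and 555 higher. INHBA was then at -1.51, and 5 lists and 9 sections passed their tests. The camera and fry alternatives were not run, because a gene set test is void on called genes. In simulation 40% of genes changed by 1.5-fold were recovered at this depth.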

Other observations

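The pathways and genes of these first paragraphs were chosen after their values were seen, as were the tests of TMM on the mitosis genes and of macrophage markers. Among 141 KEGG pathways with at least 10 listed genes, 19 differed in direction from the rest of the 806 annotated genes (Fisher's exact test, Benjamini-Hochberg adjusted). All 10 genes of cytosolic DNA sensing were higher (adjusted p = 0.0010), and 16 of 19 IL-17 pathway genes (adjusted p = 8.0e-04), while 19 of 21 cAMP pathway genes were lower (adjusted p = 0.044). The herpes simplex virus 1 pathway had 39 genes higher and 10 lower (adjusted p = 1.1e-07), and 17 of its higher genes are zinc finger genes by name. Its 32 genes not named as zinc fingers were also mostly higher, 22 against 10 lower. Zinc finger genes, taken by symbol or protein name, were higher in 19 of 22 cases, against 33.5% of the other listed genes. The median was 2.48-fold among the higher zinc finger genes.

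Several abundant transcripts outside the named rule changed. IGFBP5, which binds insulin-like growth factors, fell from 1071 ± 59.2 to 226 ± 47.2 FPKM and TM4SF1, a membrane protein, rose from 61.7 ± 1.32 to 651 ± 111 FPKM (n = 3 each). A serum amyloid A-like gene, LOC101121216, rose from 15.1 ± 3.02 to 240 ± 23.6 FPKM and a second, LOC105604171, from 11.1 ± 3.10 to 136 ± 1.23 FPKM; reads of such near-identical copies can be split between them, so each level is uncertain. SLC6A17 had 1905, 2046 and 1969 counts in siNC and 30, 341 and 305 in siINHBA, and KIAA0754 had 107, 765 and 327 counts in siINHBA; at equal depth the highest siINHBA library was 10.4 and 6.55 times the lowest.

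The fall of mitosis genes was weighed against library scaling and transcript length. With TMM over the listed genes 29 of the 34 genes were still lower and past the threshold. Their median log2 fold change moved from -2.23 to -1.14, so scaling alone did not account for the fall. That move is not evidence of a scaling error in the recovered depth. TMM centres the table on called genes and had a bias of 1.01 when the authors' fold changes were simulated as true. Of 10000 random sets of listed genes matched on transcript length implied by count over FPKM, none had a median as low as -2.23 (lowest -1.65, permutation p = 1e-04, the smallest these draws can give). Loss of INHBA and an effect of this siRNA apart from INHBA both stay open as untested, since the design has 1 siRNA group.

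The rise of inflammatory genes was weighed in the same way. None of 10000 length-matched sets had a median as high as 2.36 (highest 1.93, permutation p = 1e-04, the smallest these draws can give). Of 20 macrophage markers 4 were listed, and all 4 were lower (C1QA from 2.23 to 0.25 FPKM, C1QC from 1.00 to 0.22, MSR1 from 0.62 to 0.22 and CSF1R from 0.44 to 0.20). With TMM C1QA still passed (-1.92, edgeR adjusted p = 4.7e-04), and C1QC (-1.06), MSR1 (-0.47) and CSF1R (-0.02) did not. These values go against more macrophages, but 1 marker past the threshold under both scalings, at 2.23 FPKM, is too few to exclude it, so more macrophages in the siINHBA cultures cannot be told apart from a response of the granulosa cells. Other immune cells, a response to the transfected RNA that differs between the 2 siRNAs, and loss of INHBA stay open as untested.

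Genes that fell had longer implied transcripts than genes that rose (Spearman's rho of implied length and log2 fold change -0.28 across 1620 genes, which are not independent replicates). Long cell cycle genes were not the source, since without 129 of them rho was -0.29 over 1491 genes. A difference in RNA integrity between the groups was not tested. As for the count of passing genes, 1 of the 10 splits of the 6 libraries, the real one, gave 1620 genes and the highest of the other splits gave 0; 10 splits are too few for a share under 0.05, and the genes had been selected on the real split.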
